A study of Mus musculus with 10 samples.

How the data were processed

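RNA was sequenced from mammary epithelial cells of FVB mice in 10 libraries of 4 genotypes: NIC (2 libraries), NIC-Prmt1 (3), NIC-Carm1 (3) and NIC-Prmt6 (2). The labels do not spell out NIC. In the other genotypes a protein arginine methyltransferase (PRMT) transgene is added to it. Per the labels' protocols, the cells were freed from dissected mammary glands by enzymes and enriched by short spins, RNA was extracted with Trizol, and poly-A RNA was made into libraries with a TruSeq kit. Per the submitters' processing notes, reads were aligned to the mouse genome (mm10) with TopHat2 2.0.10, counted with HTSeq 0.6.0 and compared with DESeq 1.18.0. The annotation, the strand setting and any filter are not given in the sources used here. Genes that overlap a neighbour, or that share reads with a close copy (Apol9a and Apol9b, Hspa1a and Hspa1b, the casein genes), are therefore uncertain as single genes.

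The deposited table gives a normalised signal for 16290 genes in each library. In each column, 100% of the deposited values were whole multiples of that library's smallest step within a tolerance of 0.01, so the signal is the read count per gene that the authors obtained, divided by a size factor per library. Multiplying by that factor recovered whole reads. Every gene in the table had at least 10 recovered reads in its highest library, so genes below that level are missing from the table. The recovered reads came to between 21589300 and 30260900 per library. At that depth, counting noise limits only genes with few reads, and 3 reads in a library was taken as the floor. Ratios of reads with intervals are given for genes where no library of a group had more than 3 reads. Intervals on reads are exact 95% binomial intervals and cover counting error only, since the reads carry no molecular identifiers.

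The main test was limma-trend on log2(value + 1), in R 4.3.3 with limma 3.58.1, for the 15694 genes with a value of at least 10 in at least 2 libraries. All 10 libraries entered a single fit with 4 group means (6 residual degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The design written before the data were examined named edgeR for raw counts and limma-trend for a file without them. For such a file it also allowed the count test on recovered reads as an added alternative. The file held no raw counts, so limma-trend was used, with the filter on values in place of a filter on counts. It was tested on simulated counts for the real genes, with 200 genes changed. In the simulated NIC-Prmt1 against NIC comparison of 15495 genes it recovered 61% of genes changed 2-fold and 86% of genes changed 4-fold, with 7 false calls among 154. In NIC-Carm1 against NIC (15491 genes) it recovered 69% and 83%, with 7 false calls among 159. In NIC-Prmt6 against NIC (15487 genes) it recovered 55% and 87%, with 7 false calls among 149. Every simulated library was drawn independently, without nearly identical libraries or genes that move together, so these rates may not hold for the real data.

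The 6 comparisons between the 4 groups were made. Values are given as mean ± SD of the normalised read count. Log2 fold changes are given ± the standard error from limma, and every adjusted p of a gene is from limma. For each comparison with NIC, genes were picked for naming from the targeted PRMT genes, the 8 largest rises and 8 largest falls, and the 2 members with the smallest adjusted p from each gene list with a changed member. A top rise or fall had to pass the threshold, reach a mean log2 CPM of at least 1, have every library of either group beyond every library of the other, and carry no predicted or clone name. Between PRMT groups, 4 rises and 4 falls were taken, with list members only from lists called by camera. Of these, examples whose call held under every alternative were preferred, which was decided after the data were seen. The text gives examples, and not every gene picked is reported here. A total of 33 gene lists of cell types and pathways were fixed with the design, and 32 had enough members in the table to be tested; 13 list genes were not in the table. Lists were tested with camera on log2(value + 1) at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a comparison. Another 8 lists were written after the data were seen and are used in the closing section only.

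Library pairs were compared by a chi-square of their recovered reads over genes. The alternatives tried were DESeq2 1.42.0 and voom with quality weights on recovered reads, fits on the 2 compared groups alone, a replicate block, upper-quartile rescaling, other pseudocounts (0.5 and 5), no filter and a stricter filter (a value of at least 50), a fold threshold, and leaving out each library. Added after the data were seen were edgeR 4.0.16 on recovered reads, TMM rescaling of the deposited values (which already carry DESeq size factors), and averaging of near-identical libraries. Gene positions are from the GRCm38 annotation, the assembly that mm10 names, and all 161 genes looked up had a single position. Nothing in the labels says that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.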

Results

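The study asked which genes change in mammary epithelial cells when an arginine methyltransferase is overexpressed on the NIC genotype, a background shared by all 10 libraries. PRMT1, CARM1 and PRMT6 each place asymmetric dimethyl marks on arginines of histones and other proteins. NIC and NIC-Prmt6 had 2 libraries each, NIC-Prmt1 and NIC-Carm1 had 3 each, and these numbers hold as n for every mean below. The recovered reads ranged from 21589300 (NIC replicate 2) to 30260900 (NIC-Prmt6 replicate 2). The 10 most abundant genes held between 5.04% and 8.84% of the reads of a library. Transferrin (Trf) led in the NIC and NIC-Carm1 libraries, and the elongation factor gene Eef1a1 led in the NIC-Prmt1 and NIC-Prmt6 libraries.

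Of the 3 targeted genes, only Prmt6 was higher in its own group than in each other group. Prmt6 (chromosome 3, 110246109 to 110250998, minus strand, GRCm38, protein coding) had a normalised read count of 891 ± 25.6 (SD, n = 2) in NIC-Prmt6 and 419 ± 45.1 (SD, n = 2) in NIC, a log2 fold change of 1.09 ± 0.20 (adjusted p = 0.00321). Carm1 (chromosome 9, 21546894 to 21592623, plus strand) was at 2316 ± 167 (SD, n = 3) in NIC-Carm1 and 1562 ± 7.33 (SD, n = 2) in NIC, a log2 fold change of 0.57 ± 0.09 (adjusted p = 0.00490). Carm1 was also higher than in NIC in the other PRMT groups, by 0.46 ± 0.09 in NIC-Prmt1 (adjusted p = 0.00639) and by 0.60 ± 0.10 in NIC-Prmt6 (adjusted p = 0.00204). Against NIC-Carm1, Carm1 was not shown to differ in NIC-Prmt1 (adjusted p = 0.379) or in NIC-Prmt6 (adjusted p = 0.814). Prmt1 (chromosome 7, 44975989 to 44986568, minus strand) was at 2975 ± 278 (SD, n = 3) in NIC-Prmt1 and 2876 ± 284 (SD, n = 2) in NIC, a log2 fold change of 0.05 ± 0.12 (adjusted p = 0.784). The Prmt6 difference from NIC and from NIC-Carm1 passed in every alternative, with an adjusted p up to 0.0436 and 0.0148. That from NIC-Prmt1 ended without either NIC-Prmt6 library and on averaging (adjusted p = 0.105, and from 1.16e-10 to 0.105 over all alternatives). The Prmt6 level therefore goes with the NIC-Prmt6 label, less firmly against NIC-Prmt1. It does not settle that label, since 1441 genes rose at least 2-fold in NIC-Prmt6 against NIC. The targeted genes leave the NIC-Prmt1 and NIC-Carm1 labels unchecked. All group names below therefore mean the libraries labelled so. Whether transgene reads are counted under the mouse gene is not stated in the labels. With near-identical libraries averaged, the Carm1 difference between NIC-Carm1 and NIC no longer passed (adjusted p = 0.0501).

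**Figure D1:**
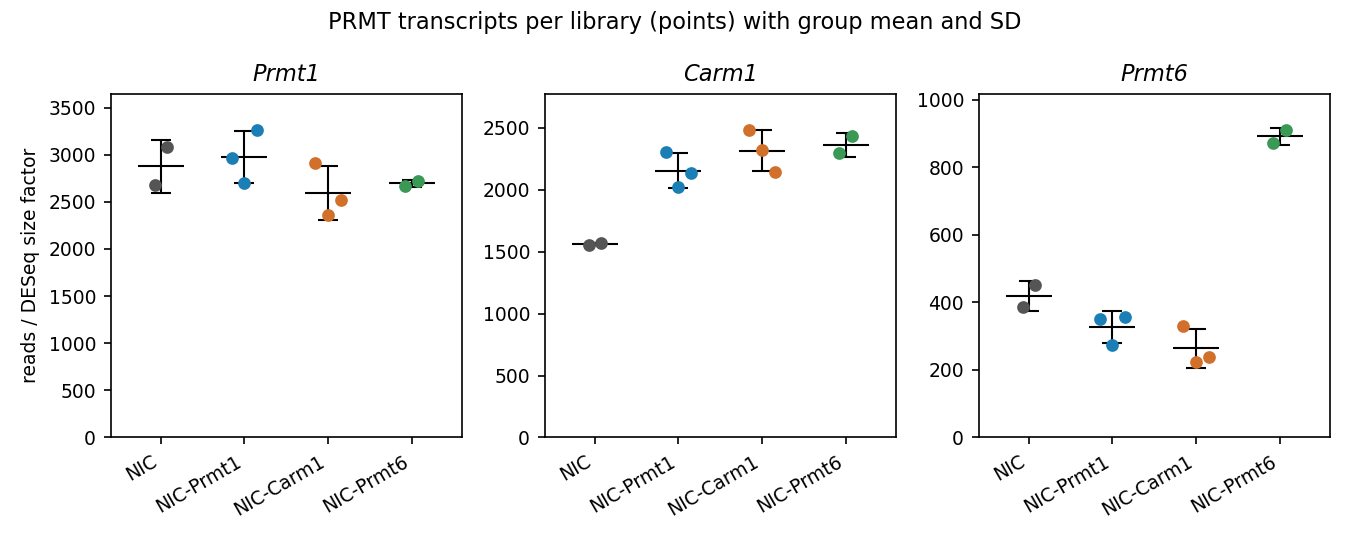
Normalised read counts (reads divided by the DESeq size factor, y axis) of Prmt1, Carm1 and Prmt6 in each library (points), with the group mean and SD (bars), by genotype (x axis). Prmt6 stands at 891 in NIC-Prmt6 against 419 in NIC, Carm1 is higher than in NIC in all 3 PRMT groups, and the 4 Prmt1 means lie between 2598 and 2975.

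Cell type markers differed between libraries of the same group as well as between groups. Milk genes summed to 45912 CPM (reads scaled to a common library total) in NIC-Carm1 replicate 1 and to 8763 and 8878 CPM in the other NIC-Carm1 libraries. Skin keratinocyte genes summed to 657 CPM in NIC-Prmt1 replicate 1 and 79.7 CPM in replicate 3, and to no more than 3.52 CPM in any other library. B cell genes were highest in NIC-Prmt1 replicate 2 (69.1 CPM) and NIC replicate 1 (45.7 CPM). The first principal component held 40.4% of the variance and ran from NIC-Carm1 and NIC to NIC-Prmt1 and NIC-Prmt6. On it NIC-Prmt1 replicate 2 lay in between, at 1.05, where NIC-Prmt1 replicates 1 and 3 lay at 65.7 and 32.9. The third, with 15.6%, put the NIC libraries at 42.5 and 48.3 and all others between -32.3 and 10.4. Replicates 2 and 3 of NIC-Carm1 and replicates 1 and 2 of NIC-Prmt6 were nearly identical, with a chi-square over its degrees of freedom of 2.73 and 2.46, where the other 6 pairs within a group gave 29.2 to 109 and pairs between groups gave 60.5 to 297. They still differed by more than counting noise and were kept as separate libraries, and each count of changed genes is also given with each of these pairs averaged to 1 library. NIC-Carm1 then has n = 2 and NIC-Prmt6 has n = 1, a lone library assumed to vary like the other groups. NIC-Prmt1 replicate 2 was as near to NIC-Carm1 replicate 3 (chi-square over its degrees of freedom 60.5) as to NIC-Prmt1 replicate 1 (60.6). It was nearer to NIC-Prmt1 replicate 3 (29.2).

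**Figure D2:**
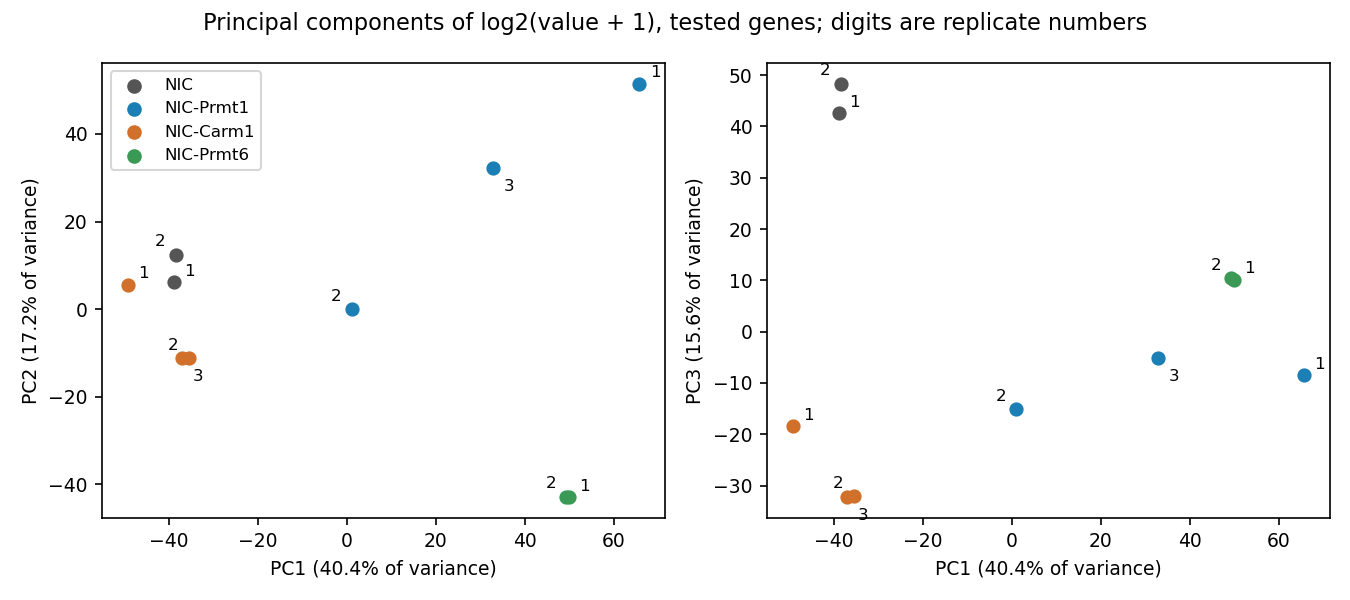
Principal components of log2(value + 1) over the tested genes, with component 1 (40.4% of the variance) on both x axes and components 2 (17.2%) and 3 (15.6%) on the y axes. Points are libraries coloured by genotype and numbered by replicate; the NIC libraries lie at 42.5 and 48.3 on component 3, above all others.

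**Figure D3:**
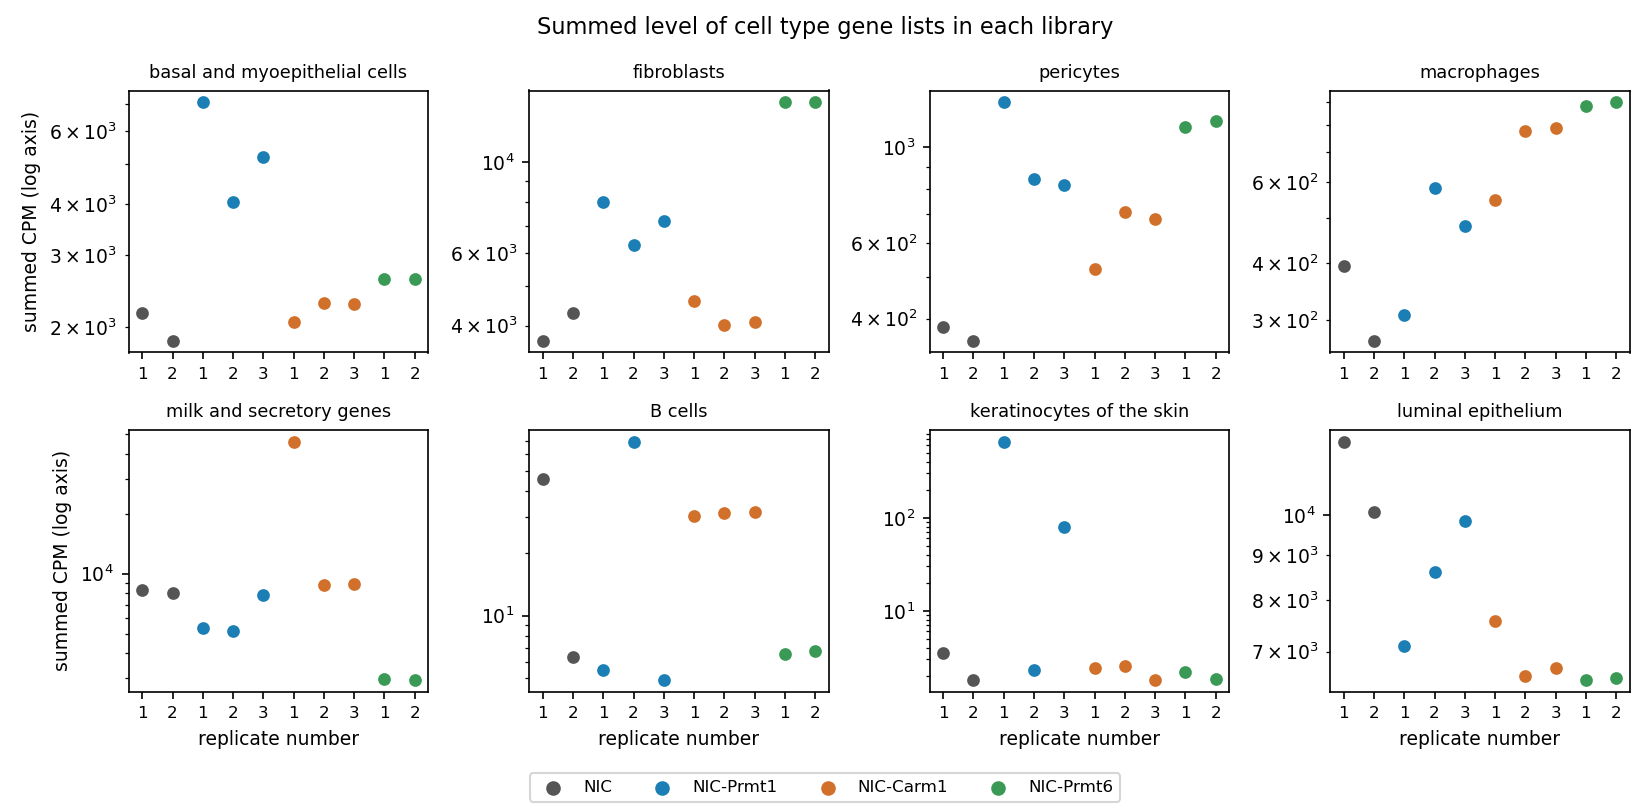
Summed CPM (log y axis) of the genes of 8 cell type lists in each library, ordered by genotype (colour) and replicate number (x axis). Fibroblast genes stand at 14000.5 and 13995 in NIC-Prmt6 against 3675 and 4298 in NIC, basal genes are highest in the 3 NIC-Prmt1 libraries, and milk genes reach 45912 in NIC-Carm1 replicate 1.

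NIC-Prmt1 against NIC compares the 3 libraries labelled NIC-Prmt1 with the 2 of NIC. Large rises were in genes of macrophages and in skin and hair keratin genes. Retnla, a secreted marker of alternatively activated macrophages (chromosome 16, 48842551 to 48844461, plus strand), rose from 17.5 ± 4.59 (SD, n = 2) to 1731 ± 808 (SD, n = 3), a log2 fold change of 6.46 ± 0.71 (adjusted p = 5.48e-04). The haemoglobin scavenger receptor gene Cd163 rose by 4.26 ± 0.62 (adjusted p = 0.00165), and the coagulation factor gene F13a1 and the lectin gene Cd209d rose by 4.16 ± 0.44 and 4.29 ± 0.82. Large falls were in Il12b, a cytokine subunit of activated antigen-presenting cells (-5.16 ± 0.74, adjusted p = 0.00159), in Chac1, a glutathione-degrading enzyme induced by amino acid stress (-4.47 ± 0.30, adjusted p = 1.06e-04), and in Cyp1a1, the classic target of the aryl hydrocarbon receptor (-4.24 ± 0.55, adjusted p = 0.00109). The chemokine gene Ccl24 had 213 recovered reads in NIC-Prmt1 and 4 in NIC, a ratio of 33.8 (exact 95% interval 13 to 125). The hair and skin keratin genes Krt25 and Krt77 had 2911 and 962 reads in NIC-Prmt1 against 1 read each in NIC, ratios of 1850 (exact 95% interval 332 to 73088) and 611 (109 to 24170). Most Krt25 reads came from NIC-Prmt1 replicate 1, whose value of 3027 compares with 41.4 and 18.6 in the other NIC-Prmt1 libraries and which also held the most skin keratinocyte transcripts. Both ratios pool the reads of a group, and their intervals do not cover such differences between libraries. With near-identical libraries averaged, the limma log2 fold changes of Krt25 and Krt77 were 6.49 and 5.89. Both keratin calls ended on leaving out either NIC library, and that of Krt77 also without NIC-Prmt1 replicate 1 or 3 and on averaging (adjusted p = 0.0625, and from 1.12e-04 to 0.337 over all alternatives).

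Epithelial lists went different ways. Of the basal and myoepithelial list, 10 of 12 rose (12 adjusted over the list alone; camera adjusted p = 2.32e-06, and adjusted p = 0.30 with an estimated correlation). Smooth muscle actin (Acta2) rose from 10879.8 ± 507 to 39297 ± 9363, by 1.82 ± 0.18, and Tagln, an actin-binding protein of contractile cells, by 0.99 ± 0.16. Some of these genes are not special to mammary epithelium: vessel-associated cells also make Acta2 and Tagln, and skin makes the basal keratins. Basal genes summed to 7064, 4039.6 and 5193 CPM in NIC-Prmt1 replicates 1 to 3, the same order as the skin genes, though replicate 2 had only 2.31 CPM of skin genes, and to 2167 and 1856 CPM in NIC. Of the genes of hormone-sensing luminal cells, 6 of 11 rose (8 adjusted over the list alone; camera adjusted p = 6.80e-04, and adjusted p = 0.274 with an estimated correlation), led by the progesterone receptor gene Pgr (1.58 ± 0.17) and the growth factor gene Areg (0.73 ± 0.09). In the luminal epithelium list, 5 of 12 fell and 3 rose (7 and 3 adjusted over the list alone; camera adjusted p = 0.0896): the adhesion gene Epcam fell (-1.14 ± 0.16) and the keratin Krt7 rose by 0.67 ± 0.11. The luminal progenitor gene Ehf and the casein gene Csn3 fell, at -1.08 and -1.32. Markers of stromal cells moved as well. All 10 endothelial and all 6 pericyte genes rose, also adjusted over the list alone (camera adjusted p = 1.31e-06 and 2.32e-06, and adjusted p = 0.274 for both with an estimated correlation), with Kdr at 1.30 ± 0.14 and Kcnj8 at 2.26 ± 0.14. Of the fibroblast genes, 8 of 12 rose (9 adjusted over the list alone; camera adjusted p = 1.04e-04, and adjusted p = 0.274 with an estimated correlation), with Col6a3 at 1.48 ± 0.17. In the mesenchymal list, 6 of 12 rose (10 adjusted over the list alone; camera adjusted p = 2.31e-04, and adjusted p = 0.274 with an estimated correlation), with the cadherin Cdh2 at 1.34 ± 0.25 and the transcription factor Snai1 at 0.80 ± 0.15. Among 11 macrophage genes, 2 rose, Cd163 and the mannose receptor gene Mrc1, and none fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.187); the median of the other 9 was 0.074. Without NIC replicate 2 the Mrc1 call ended (adjusted p = 0.0588).

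Genes of the interferon response were lower in NIC-Prmt1 than in NIC. Of this list, 14 of 16 fell (15 adjusted over the list alone; camera adjusted p = 2.15e-07, and adjusted p = 0.30 with an estimated correlation), among them the regulator Irf7 (-2.33 ± 0.26) and the antiviral enzyme gene Oas1a (-2.23 ± 0.29). Of the NF-kB and inflammatory genes, 7 of 16 fell (7 adjusted over the list alone; camera adjusted p = 0.00254, and adjusted p = 0.274 with an estimated correlation), led by the neutrophil chemokines Cxcl2 (-2.41 ± 0.09) and Cxcl1 (-1.62 ± 0.14), while Il6 rose. Some metabolic and stress genes fell too. Of the glycolysis and hypoxia genes, 7 of 13 fell (7 adjusted over the list alone; camera adjusted p = 0.0110, and adjusted p = 0.30 with an estimated correlation), with the hypoxia-induced Egln3 at -1.98 ± 0.19. Of the lipid synthesis genes, 5 of 14 fell (7 adjusted over the list alone; camera adjusted p = 2.71e-04, and adjusted p = 0.30 with an estimated correlation), with the sterol sensor gene Insig1 at -1.91 ± 0.10. Of the stress response genes of unfolded proteins and amino acid shortage, 6 of 12 fell (6 adjusted over the list alone; camera adjusted p = 5.15e-05, and adjusted p = 0.274 with an estimated correlation), with the asparagine synthetase gene Asns at -1.28 ± 0.13. Among cell cycle genes, 7 of 24 fell (12 adjusted over the list alone; camera adjusted p = 2.31e-04, and adjusted p = 0.490 with an estimated correlation). Of 11 ErbB receptor and ligand genes, 6 fell and 2 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.0246, and adjusted p = 0.274 with an estimated correlation). The ligand Tgfa fell, at -1.08, and the ligands Areg and Btc rose. Of the immediate early genes, 9 of 14 rose (9 adjusted over the list alone; camera adjusted p = 0.0119, and adjusted p = 0.490 with an estimated correlation), with Btg2 at 1.5 ± 0.18, and 3 fell, Ier3 and the heat shock genes Hspa1a and Hspa1b. Also called by camera were skeletal muscle genes (3 of 13 up, 0 adjusted over the list alone), matrix proteases and inhibitors (5 of 14 up and 3 down; 8 and 3 adjusted over the list alone) and histone genes (3 of 8 down, 3 adjusted over the list alone). With an estimated correlation, adjusted p for these last lists ran from 0.30 to 0.490.

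Across all tested genes, 4645 changed between NIC-Prmt1 and NIC, 2387 higher and 2258 lower (1988 and 2099 with voom), and 891 of the rises and 529 of the falls were at least 2-fold. Camera called 17 of the 32 lists, 9 up and 8 down. None of these calls held with an estimated correlation, and fry called 17. The count of changed genes was 2601 with near-identical libraries averaged, 2585 without NIC replicate 1 and 2277 without NIC replicate 2. Of the 69 named genes that passed, 52 kept their call in each alternative fit. Averaging left 14 interferon, 6 protein stress, 5 lipid, 5 glycolysis, 4 NF-kB and 2 cell cycle genes lower, and 10 endothelial, 6 pericyte, 8 basal, 6 fibroblast, 5 mesenchymal, 5 hormone-sensing and 7 immediate early genes higher.

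NIC-Carm1 against NIC does the same for the libraries labelled NIC-Carm1. Macrophage genes were again among the 8 largest rises: Retnla from 17.5 ± 4.59 (SD, n = 2) to 1882 ± 1276 (SD, n = 3), by 6.27 ± 0.71 (adjusted p = 9.57e-04), the ficolin gene Fcna by 4.51 ± 0.39 (adjusted p = 3.83e-04) and Cd163 by 4.34 ± 0.62 (adjusted p = 0.00274). Large falls were in Cyp1a1 (-5.15 ± 0.55, adjusted p = 7.21e-04), Chac1 (-4.07 ± 0.30, adjusted p = 1.29e-04), the keratin gene Krt6a (-3.77 ± 0.88), Il12b (-3.71 ± 0.74), the cytokine gene Il11 (-3.55 ± 0.47), the transcription factor gene Pou3f1 (-3.51 ± 0.35) and Epgn, a ligand of the EGF receptor (-3.38 ± 0.27). The calls of Krt6a and Il12b (adjusted p = 0.0195 and 0.0109) ended without either NIC library, that of Il12b also with the 2 groups alone (adjusted p from 9.57e-07 to 0.0656 over all alternatives), and that of Krt6a also without NIC-Carm1 replicate 2 or 3 and on averaging (adjusted p = 0.0998, and from 2.27e-04 to 0.134 over all alternatives). Ccl24 had 278 reads against 4, a ratio of 40.5 (exact 95% interval 15.6 to 150), and its call ended on averaging (adjusted p = 0.0628, and from 2.72e-06 to 0.0628 over all alternatives). Some inflammatory genes fell. Of the NF-kB list, 9 of 16 fell (12 adjusted over the list alone; camera adjusted p = 4.29e-07, and adjusted p = 0.123 with an estimated correlation), with Cxcl2 at -2.23 ± 0.09 and Cxcl1 at -2.17 ± 0.14. Of the ErbB receptors and ligands, 5 of 11 fell (6 adjusted over the list alone; camera adjusted p = 0.00466, and adjusted p = 0.173 with an estimated correlation): the ligands Hbegf (-1.85 ± 0.15), Areg (-0.74 ± 0.09), Ereg and Tgfa, and the receptor gene Egfr. Erbb2, the gene of the receptor also called Neu, was the member that rose (0.90 ± 0.27, adjusted p = 0.0480). That call ended without NIC replicate 1, NIC-Prmt1 replicate 3 or any NIC-Carm1 or NIC-Prmt6 library, with edgeR and on averaging (adjusted p = 0.183, and from 0.00736 to 0.313 over all alternatives).

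Of the p53 targets and cell cycle inhibitors, 7 of 14 fell (9 adjusted over the list alone; camera adjusted p = 0.00466, and adjusted p = 0.173 with an estimated correlation), with the inhibitor gene Cdkn1a at -1.43 ± 0.10. Among cell cycle genes, 3 of 24 rose (3 adjusted over the list alone; camera adjusted p = 7.37e-04, and adjusted p = 0.771 with an estimated correlation): the replication genes Mcm2, Mcm6 and Rrm2, while Pcna, the sliding clamp of DNA polymerase, fell. Of the lipid and cholesterol synthesis genes, 10 of 14 fell (10 adjusted over the list alone; camera adjusted p = 7.06e-05, and adjusted p = 0.484 with an estimated correlation), with Insig1 at -1.51 ± 0.10 and the squalene synthase gene Fdft1 at -0.93 ± 0.09. Of the unfolded protein and amino acid stress genes, 6 of 12 fell (8 adjusted over the list alone; camera adjusted p = 4.10e-04, and adjusted p = 0.484 with an estimated correlation), with the chaperone partner Dnajb9 at -0.99 ± 0.14. Of the glycolysis and hypoxia genes, 3 of 13 fell (5 adjusted over the list alone; camera adjusted p = 0.0133, and adjusted p = 0.484 with an estimated correlation), with the glucose transporter gene Slc2a1 at -1.16 ± 0.16. The urokinase gene Plau and its receptor gene Plaur fell, at -1.09 ± 0.10 and -1.98 ± 0.18, and the heat shock genes Hspa1a and Hspa1b at -1.84 ± 0.19 and -1.96 ± 0.21. Among cell types, 6 of 12 luminal epithelial genes fell (6 adjusted over the list alone; camera adjusted p = 4.10e-04, and adjusted p = 0.484 with an estimated correlation). Of the pericyte genes, 3 of 6 rose (5 adjusted over the list alone; camera adjusted p = 1.47e-04, and adjusted p = 0.484 with an estimated correlation), with Kcnj8 at 1.5 ± 0.14. Of the macrophage genes, 3 of 11 rose (8 adjusted over the list alone; camera adjusted p = 2.07e-04, and adjusted p = 0.493 with an estimated correlation). Of the Schwann cell genes, 4 of 7 fell (5 adjusted over the list alone; camera adjusted p = 0.00383, and adjusted p = 0.484 with an estimated correlation), with the myelin gene Mbp at -1.39 ± 0.24. Of the skeletal muscle genes, 2 of 13 rose (3 adjusted over the list alone; camera adjusted p = 0.00106, and adjusted p = 0.722 with an estimated correlation). No basal or endothelial gene and no interferon response gene passed the threshold over all genes (camera adjusted p = 0.762, 0.743 and 0.608).

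In all, 2513 genes changed between NIC-Carm1 and NIC, 1044 higher and 1469 lower (1308 and 1238 with upper-quartile rescaling), of which 243 and 338 by at least 2-fold. Camera called 12 lists, 4 up and 8 down. None held with an estimated correlation, and fry called 8. This count rests on few libraries: it was 340 with near-identical libraries averaged, 709 without NIC replicate 1, 1367 without NIC replicate 2, 1051 and 1077 without NIC-Carm1 replicates 2 and 3, and 1529 and 1530 without NIC-Prmt6 replicates 1 and 2. Of the 53 named genes that passed, 26 kept their call in each alternative fit. Averaging left 3 NF-kB, 3 ErbB, 1 p53 list, 4 lipid, 3 protein stress, 2 glycolysis, 2 Schwann cell and no luminal genes lower, and 3 pericyte, 1 macrophage, no cell cycle and no skeletal muscle genes higher.

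NIC-Prmt6 against NIC, with 2 libraries on each side, showed higher stromal genes and higher values of many macrophage genes. Retnla rose from 17.5 ± 4.59 (SD, n = 2) to 4594 ± 129.7 (SD, n = 2), by 7.98 ± 0.77 (adjusted p = 1.37e-04), Cd163 by 6.02 ± 0.68 (adjusted p = 2.88e-04), F13a1 by 5.73 ± 0.48 (adjusted p = 9.00e-05) and the gelatinase gene Mmp9 by 5.33 ± 0.80 (adjusted p = 0.00116). Ccl24 had 435 reads against 4, a ratio of 87.7 (exact 95% interval 34 to 323). The protease inhibitor gene A2m fell, at -4.67 ± 0.90 (adjusted p = 0.00362), Dppa1 at -4.10 ± 0.67 and Chac1 at -3.63 ± 0.33. All 12 fibroblast genes rose, also adjusted over the list alone (camera adjusted p = 1.48e-08, and adjusted p = 0.182 with an estimated correlation), among them the matrix genes Lum (2.36 ± 0.18) and Col6a3 (2.29 ± 0.19). All 10 endothelial and all 6 pericyte genes rose, also adjusted over the list alone (camera adjusted p = 2.73e-06 and 6.89e-06, and adjusted p = 0.399 for both with an estimated correlation), with Kdr at 1.95 ± 0.15 and Kcnj8 at 2.64 ± 0.15. Of the mesenchymal genes, 11 of 12 rose (12 adjusted over the list alone; camera adjusted p = 3.90e-06, and adjusted p = 0.399 with an estimated correlation), with fibronectin (Fn1) at 2.75 ± 0.29 and Snai1 at 1.48 ± 0.16. Of the macrophage genes, 8 of 11 rose (9 adjusted over the list alone; camera adjusted p = 1.27e-04, and adjusted p = 0.454 with an estimated correlation), with Mrc1 at 4.57 ± 0.62. Of the adipocyte genes, 4 of 13 rose (4 adjusted over the list alone; camera adjusted p = 0.0104, and adjusted p = 0.50 with an estimated correlation), with Pparg, the master regulator of fat cells, at 2.03 ± 0.19. Of the matrix proteases and inhibitors, 8 of 14 rose (9 adjusted over the list alone; camera adjusted p = 0.00537, and adjusted p = 0.399 with an estimated correlation), with Mmp14 at 1.53 ± 0.18 and Timp2 at 1.62 ± 0.22.

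Some luminal and milk genes fell in NIC-Prmt6. Of the luminal epithelium list, 7 of 12 fell (7 adjusted over the list alone; camera adjusted p = 0.00204, and adjusted p = 0.454 with an estimated correlation), with Epcam at -1.44 ± 0.18 and the splicing factor gene Esrp1 at -0.70 ± 0.11. Of the luminal progenitor genes, 3 of 8 fell (3 adjusted over the list alone; camera adjusted p = 0.0336, and adjusted p = 0.454 with an estimated correlation), with Lcn2 at -1.94 ± 0.29 and Ehf at -0.90 ± 0.15. Of the milk genes, 6 of 14 fell (7 adjusted over the list alone; camera adjusted p = 0.00929, and adjusted p = 0.50 with an estimated correlation), with Csn3 at -2.35 ± 0.29. Among basal genes, 2 of 12 rose (1 adjusted over the list alone; camera adjusted p = 0.830). Pgr rose by 1.46 ± 0.19. Of the Notch targets and ligands, 6 of 10 rose (6 adjusted over the list alone; camera adjusted p = 0.0354, and adjusted p = 0.454 with an estimated correlation), with the vessel-associated Dll4 at 1.15 ± 0.11 and Notch4 at 1.71 ± 0.21. Of the interferon response genes, 12 of 16 fell (13 adjusted over the list alone; camera adjusted p = 4.67e-05, and adjusted p = 0.454 with an estimated correlation), with Irf7 at -2.03 ± 0.28. In the NF-kB list the members went both ways (camera adjusted p = 0.830): Il6 rose by 1.30 ± 0.12 and Cxcl2 fell, at -1.07 ± 0.10. Of the unfolded protein and amino acid stress genes, 10 of 12 fell (10 adjusted over the list alone; camera adjusted p = 3.32e-05, and adjusted p = 0.399 with an estimated correlation), with the pseudokinase gene Trib3 at -2.88 ± 0.30. Of the glycolysis and hypoxia genes, 7 of 13 fell (7 adjusted over the list alone; camera adjusted p = 0.0225, and adjusted p = 0.454 with an estimated correlation), with Egln3 at -3.14 ± 0.21; Hk2 and Adm rose. The desaturase gene Scd2 and Insig1 fell, at -1.81 and -1.29. Also called down were 5 of 24 cell cycle genes (4 adjusted over the list alone), 4 of 8 histone genes (5 adjusted over the list alone) and 4 of 7 Schwann cell genes (5 adjusted over the list alone), with adjusted p of 0.50, 0.454 and 0.454 with an estimated correlation.

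In all, 5778 genes changed between NIC-Prmt6 and NIC, 2984 higher and 2794 lower (2858 and 2965 with upper-quartile rescaling), of which 1441 and 696 by at least 2-fold. Camera called 17 lists, 8 up and 9 down. None held with an estimated correlation, and fry called 19. The count of changed genes was 1664 with near-identical libraries averaged, 3287 without NIC replicate 2, and 2661 and 2753 without NIC-Prmt6 replicates 1 and 2. Of the 71 named genes that passed, 49 kept their call in each alternative fit. Averaging left all 12 fibroblast and 6 pericyte genes higher, with 8 endothelial, 6 mesenchymal, 3 macrophage, 2 adipocyte, 7 matrix protease and 5 Notch genes, and 3 interferon, 3 protein stress, 5 glycolysis, 3 luminal, 2 luminal progenitor, 2 milk, 1 Schwann cell, no cell cycle and no histone genes lower.

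**Figure D4:**
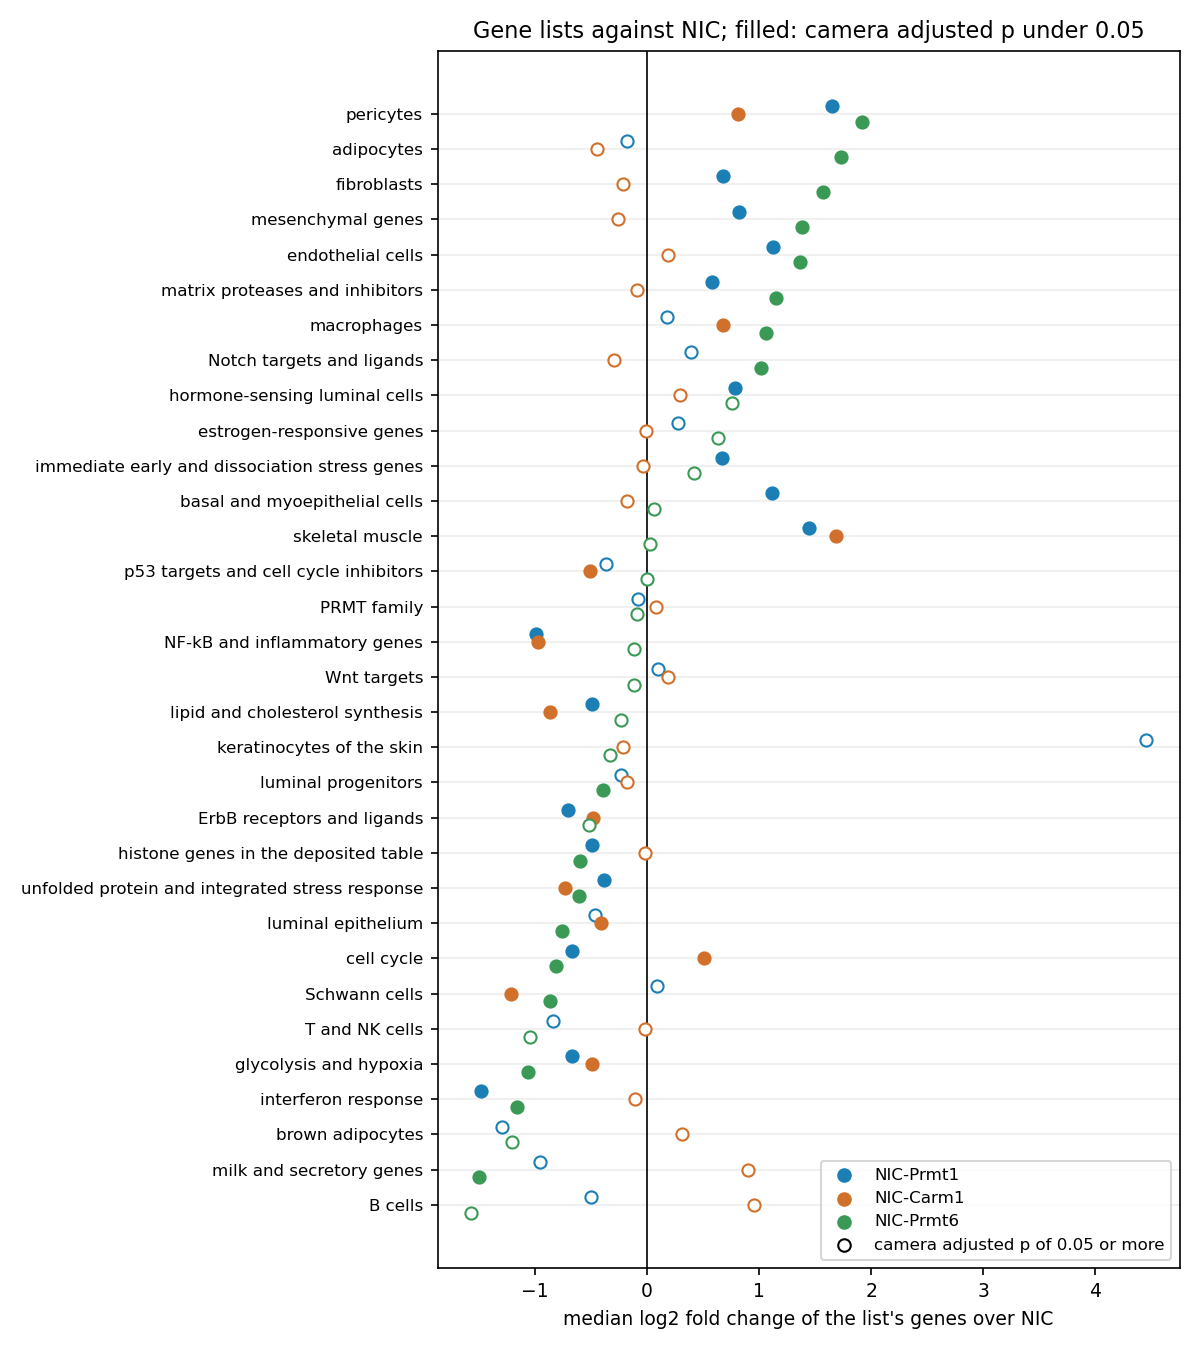
Median log2 fold change over NIC (x axis) of the genes of each list (y axis) in the 3 PRMT groups (colours); filled points have a camera adjusted p under 0.05 at the preset correlation, and no list has one with an estimated correlation. Pericyte genes lie at 1.65, 0.81 and 1.91 in NIC-Prmt1, NIC-Carm1 and NIC-Prmt6, and interferon response genes at -1.48, -0.11 and -1.16.

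The same genes changed against NIC in all 3 PRMT groups more often than independent lists would. Shared changes numbered 989, of which 457 rose and 532 fell, where independent lists of these sizes would share 30.2 and 37.6. Retnla, Ccl24, Cd163, Cd209d and F13a1 had the largest mean rises, and Chac1 fell, at -4.47, -4.07 and -3.63 in NIC-Prmt1, NIC-Carm1 and NIC-Prmt6. Cxcl2, Insig1 and Egln3 also fell in all 3 groups. NIC-Prmt1 and NIC-Prmt6 shared 1725 rises and 1586 falls, with 11 genes going opposite ways, against 454, 402 and 854 for independent lists. NIC-Prmt1 and NIC-Carm1 shared 585 and 795 with 28 opposite, against 159, 211 and 374. NIC-Carm1 and NIC-Prmt6 shared 547 and 646 with 129 opposite, against 199, 262 and 465. In 50 simulated draws, all 10 libraries, NIC included, were drawn around each gene's mean over all libraries, with no group changed. The comparisons then shared at most 1 gene. Few genes can pass the threshold where no group is changed, so this number sets no bound for the 989. The covariance of fold changes across genes, which are not independent replicates, was 0.464 for NIC-Prmt1 with NIC-Prmt6, 0.227 for NIC-Prmt1 with NIC-Carm1 and 0.214 for NIC-Carm1 with NIC-Prmt6, against simulated values of 0.0661, 0.0664 and 0.0668. The differences were 0.398, 0.160 and 0.148. The draws used the spread of the main fit, in which the near-identical libraries count separately. If these are repeats of a single preparation, that spread and the simulated covariances may be too low. The Pearson correlations were 0.717, 0.505 and 0.406, against simulated values of 0.548, 0.601 and 0.553, so both with NIC-Carm1 lay below the simulated ones. The share of genes with the same sign was 80.7%, 68.5% and 62.9%, against simulated values of 68.4%, 70.5% and 68.4%. The 2 NIC libraries cannot be split into parts of 2, so part of the excess in shared genes and covariance may come from the shared controls. The number of genes changed the same way in all 3 comparisons with NIC was 115 with near-identical libraries averaged, 358 and 485 without NIC replicates 1 and 2, 479 and 494 without NIC-Carm1 replicates 2 and 3, and 435 and 443 without NIC-Prmt6 replicates 1 and 2.

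NIC-Prmt1 against NIC-Carm1 tests the difference between these groups directly. Most cell cycle and interferon genes were lower and most basal and stromal genes higher in NIC-Prmt1. Areg was at 7455 ± 627 (SD, n = 3) in NIC-Prmt1 and 2684 ± 97.6 (SD, n = 3) in NIC-Carm1, a log2 fold change of 1.47 ± 0.08 (adjusted p = 5.08e-05), and Pgr was higher by 1.52 ± 0.15 (adjusted p = 9.41e-04). The neuronal adhesion genes Dscam and Nrxn3 were higher by 3.81 ± 0.39 (adjusted p = 9.70e-04) and 3.29 ± 0.47 (adjusted p = 0.00200). Of the cell cycle genes, 20 of 24 fell (21 adjusted over the list alone; camera adjusted p = 3.18e-10, and adjusted p = 0.367 with an estimated correlation), with Mcm2 at -0.81 ± 0.11 and Rrm2 at -1.31 ± 0.18. Of the interferon response genes, 15 of 16 fell (15 adjusted over the list alone; camera adjusted p = 1.83e-08, and adjusted p = 0.367 with an estimated correlation), with Oasl2 at -1.60 ± 0.21 and Oas1a at -1.89 ± 0.26. Of the hormone-sensing genes, 3 of 11 rose (5 adjusted over the list alone; camera adjusted p = 0.00154, and adjusted p = 0.301 with an estimated correlation). Of the basal genes, 11 of 12 rose (12 adjusted over the list alone; camera adjusted p = 7.02e-08, and adjusted p = 0.315 with an estimated correlation), with the contractile gene Cnn1 at 1.39 ± 0.15. All 10 endothelial and all 6 pericyte genes were higher, also adjusted over the list alone (camera adjusted p = 1.36e-07 and 5.19e-04, and adjusted p = 0.315 and 0.367 with an estimated correlation), with Cdh5 at 0.95 ± 0.12 and Pdgfrb at 0.90 ± 0.15.

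Of the fibroblast genes, 10 of 12 rose (10 adjusted over the list alone; camera adjusted p = 1.30e-06, and adjusted p = 0.301 with an estimated correlation), with Col6a3 at 1.36 ± 0.15 and Fbln1 at 1.14 ± 0.13. Of the mesenchymal genes, 10 of 12 rose (10 adjusted over the list alone; camera adjusted p = 1.94e-06, and adjusted p = 0.301 with an estimated correlation), with Twist1 at 1.40 ± 0.19. Of the Notch targets and ligands, 8 of 10 rose (8 adjusted over the list alone; camera adjusted p = 5.19e-04, and adjusted p = 0.315 with an estimated correlation), with Dll4 at 1.13 ± 0.09 and Nrarp at 1.32 ± 0.15. Of the immediate early genes, 10 of 14 rose (10 adjusted over the list alone; camera adjusted p = 5.19e-04, and adjusted p = 0.371 with an estimated correlation), with Fosb at 1.45 ± 0.18. Of the matrix proteases and inhibitors, 7 of 14 rose (7 adjusted over the list alone; camera adjusted p = 0.00542, and adjusted p = 0.315 with an estimated correlation), with Plaur at 1.19 ± 0.16. Of the Schwann cell genes, 5 of 7 rose (5 adjusted over the list alone; camera adjusted p = 0.0369, and adjusted p = 0.462 with an estimated correlation): the myelin gene Prx was higher by 1.64 ± 0.23 and the transcription factor gene Sox10 lower, at -0.96 ± 0.12. Of the milk genes, 6 of 14 fell (10 adjusted over the list alone; camera adjusted p = 6.29e-04, and adjusted p = 0.455 with an estimated correlation), with Csn3 lower, at -1.24 ± 0.24; NIC-Carm1 replicate 1 held 45912 CPM of milk transcripts. Among the other lists called were estrogen-responsive genes (6 of 13 up and 2 down; 7 and 2 adjusted over the list alone), histone genes (4 of 8 down, 5 adjusted over the list alone), macrophage genes (1 of 11 down, 0 adjusted over the list alone) and skin keratinocyte genes (0 of 5 passing over all genes, 4 up adjusted over the list alone, and highest in NIC-Prmt1 replicate 1). With an estimated correlation these gave adjusted p from 0.371 to 0.484. Erbb2, singled out after its values were seen, was lower in NIC-Prmt1, at -1.59 ± 0.24 (adjusted p = 0.00254).

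In all, 4199 genes differed between NIC-Prmt1 and NIC-Carm1, 2340 higher in NIC-Prmt1 and 1859 lower, of which 781 and 472 by at least 2-fold. Camera called 17 lists, 12 up and 5 down. None held with an estimated correlation, and fry called 16. The count was 1355 with near-identical libraries averaged, 2664 without NIC-Prmt1 replicate 1, and 2693 and 2626 without NIC-Carm1 replicates 2 and 3. Of the 37 named genes that passed, 28 kept their call in each alternative fit. Averaging left 13 cell cycle, 8 interferon, 2 milk and no histone genes lower, and 8 basal, 10 endothelial, 3 pericyte, 7 fibroblast, 6 mesenchymal, 5 Notch, 3 immediate early, 6 matrix protease and 3 hormone-sensing genes higher. The scavenger receptor genes Marco and Stab2, lower in NIC-Prmt1 at -6.02 ± 1.42 and -5.58 ± 1.26, lost theirs on averaging (adjusted p = 0.0640 and 0.0574).

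NIC-Prmt1 against NIC-Prmt6 differed in inflammatory, stromal and basal genes. The monocyte chemokine gene Ccl2 was at 868 ± 37.4 (SD, n = 3) in NIC-Prmt1 and 4032 ± 19.8 (SD, n = 2) in NIC-Prmt6, lower, at -2.22 ± 0.19 (adjusted p = 4.39e-04), and Cxcl2 was lower, at -1.35 ± 0.09 (adjusted p = 1.43e-04). Of the NF-kB genes, 5 of 16 fell (7 adjusted over the list alone; camera adjusted p = 1.24e-05, and adjusted p = 0.0972 with an estimated correlation). Of the fibroblast genes, 11 of 12 fell (11 adjusted over the list alone; camera adjusted p = 9.98e-10, and adjusted p = 0.0972 with an estimated correlation), with Lum lower, at -1.62 ± 0.17. Of the macrophage genes, 5 of 11 fell (10 adjusted over the list alone; camera adjusted p = 5.67e-06, and adjusted p = 0.399 with an estimated correlation). Of the basal genes, 8 of 12 rose (11 adjusted over the list alone; camera adjusted p = 1.70e-09, and adjusted p = 0.390 with an estimated correlation), with Cnn1 at 1.36 ± 0.17 and Acta2 at 1.09 ± 0.18. Of the mesenchymal genes, 5 of 12 fell (6 adjusted over the list alone; camera adjusted p = 4.96e-04, and adjusted p = 0.390 with an estimated correlation), with Fn1 lower, at -1.86 ± 0.27. Of the p53 targets and cell cycle inhibitors, 4 of 14 fell (6 adjusted over the list alone; camera adjusted p = 0.00131, and adjusted p = 0.0972 with an estimated correlation). The growth factor gene Fgf10 and the BMP-binding gene Bmper were lower, at -3.25 ± 0.49 and -2.92 ± 0.37, and the inner root sheath keratin gene Krt71 was higher by 6.71 ± 1.47; NIC-Prmt1 replicate 1 held the most skin and hair keratin transcripts. Prmt6 itself was lower, at -1.46 ± 0.19 (adjusted p = 0.00300). The other lists called were adipocyte genes (2 of 13 down, 9 adjusted over the list alone) and matrix proteases and inhibitors (4 of 14 down and 1 up, the same adjusted over the list alone), lower, and Schwann cell (3 of 7, 5 adjusted over the list alone), luminal (2 of 12, 4 adjusted over the list alone), skeletal muscle (1 of 13, 2 adjusted over the list alone), milk (1 of 14, 2 adjusted over the list alone) and skin keratinocyte genes (0 of 5, 4 adjusted over the list alone), higher. With an estimated correlation these gave adjusted p from 0.390 to 0.640.

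In all, 1175 genes differed between NIC-Prmt1 and NIC-Prmt6, 399 higher in NIC-Prmt1 and 776 lower (567 and 562 with upper-quartile rescaling), of which 174 and 300 by at least 2-fold. Camera called 13 lists, 6 up and 7 down. None held with an estimated correlation, and fry called 7. The count rests on the near-identical NIC-Prmt6 libraries: 21 genes passed with near-identical libraries averaged, 47 and 48 without NIC-Prmt6 replicates 1 and 2, and 444 without NIC-Prmt1 replicate 3, while 2237 passed without NIC-Prmt1 replicate 1 and 1982 without NIC-Carm1 replicate 1. Of the 31 named genes that passed, only Ccl2 and Cxcl2 kept their call in each alternative fit, and all others named above, Prmt6 included, lost it with the pairs averaged. No member of a called list other than the NF-kB list then passed.

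NIC-Carm1 against NIC-Prmt6 showed most milk and cell cycle genes higher in NIC-Carm1, and most stromal and inflammatory genes lower. The casein gene Csn1s1 was at 77085 ± 113508 (SD, n = 3) in NIC-Carm1 and 722 ± 64.4 (SD, n = 2) in NIC-Prmt6, higher by 5.39 ± 1.11 (adjusted p = 0.00473), with NIC-Carm1 replicate 1 far above the others, and Csn3 was higher by 2.27 ± 0.27 (adjusted p = 2.88e-04). Fgf10, Dscam, Cyp1a1 and the calcium sensor gene Hpca were lower, at -3.94 ± 0.49, -3.92 ± 0.44, -3.81 ± 0.55 and -3.73 ± 0.44 (adjusted p from 2.23e-04 to 7.99e-04). Prmt6 was lower, at -1.77 ± 0.19 (adjusted p = 1.69e-04). Of the milk genes, 9 of 14 rose (9 adjusted over the list alone; camera adjusted p = 7.69e-05, and adjusted p = 0.443 with an estimated correlation). Of the cell cycle genes, 20 of 24 rose (21 adjusted over the list alone; camera adjusted p = 2.10e-07, and adjusted p = 0.443 with an estimated correlation), with Mcm2 at 0.85 ± 0.12 and Mcm5 at 1.13 ± 0.17, and Pcna was lower. All 12 fibroblast and all 12 mesenchymal genes were lower, also adjusted over the list alone (camera adjusted p = 2.27e-09 and 2.95e-07, and adjusted p = 0.147 and 0.15 with an estimated correlation), with Lum at -2.47 ± 0.17 and Twist1 at -2.37 ± 0.22. All 10 endothelial and all 6 pericyte genes were lower, also adjusted over the list alone (camera adjusted p = 1.88e-06 and 6.22e-04, and adjusted p = 0.392 and 0.443 with an estimated correlation), with Kdr at -1.53 ± 0.14 and Abcc9 at -1.34 ± 0.15. Of the adipocyte genes, 9 of 13 fell (9 adjusted over the list alone; camera adjusted p = 0.00111, and adjusted p = 0.443 with an estimated correlation), with Pparg at -1.96 ± 0.18.

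Of the NF-kB genes, 10 of 16 fell (10 adjusted over the list alone; camera adjusted p = 7.69e-05, and adjusted p = 0.15 with an estimated correlation), with Ccl2 at -2.87 ± 0.19 and Il6 at -1.64 ± 0.11. Of the p53 targets and cell cycle inhibitors, 7 of 14 fell (8 adjusted over the list alone; camera adjusted p = 0.00413, and adjusted p = 0.15 with an estimated correlation), with Cdkn1a at -1.19 ± 0.10 and Eda2r at -1.68 ± 0.21. Of the Notch targets and ligands, 9 of 10 fell (9 adjusted over the list alone; camera adjusted p = 7.59e-04, and adjusted p = 0.392 with an estimated correlation), with Dll4 at -2.02 ± 0.10. Of the matrix proteases and inhibitors, 9 of 14 fell (9 adjusted over the list alone; camera adjusted p = 0.00171, and adjusted p = 0.227 with an estimated correlation), with Plau at -1.62 ± 0.10. Of the immediate early genes, 6 of 14 fell (6 adjusted over the list alone; camera adjusted p = 0.0312, and adjusted p = 0.571 with an estimated correlation), with Dusp1 at -1.19 ± 0.15. Of the interferon response genes, 12 of 16 rose (13 adjusted over the list alone; camera adjusted p = 7.69e-05, and adjusted p = 0.443 with an estimated correlation). Also called up were histone genes (3 of 8, 3 adjusted over the list alone), skeletal muscle genes (3 of 13, 2 adjusted over the list alone) and B cell genes, of which Cr2 alone passed over all genes and none adjusted over the list alone. Cr2, a complement receptor gene of mature B cells, had 201 reads in NIC-Carm1 and 2 in NIC-Prmt6, a ratio of 72.7 (exact 95% interval 19.9 to 604), but its call ended on leaving out any of the 5 libraries, with edgeR and on averaging (adjusted p = 0.246, and from 4.34e-04 to 0.246 over all alternatives). With an estimated correlation these lists gave adjusted p from 0.443 to 0.641. Erbb2 was higher in NIC-Carm1 by 1.41 ± 0.27 (adjusted p = 0.00322) and lost its call on averaging (adjusted p = 0.0704, and from 7.54e-07 to 0.0704 over all alternatives).

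In all, 6157 genes differed between NIC-Carm1 and NIC-Prmt6, 2882 higher in NIC-Carm1 and 3275 lower (3535 and 2855 with upper-quartile rescaling), of which 785 and 1423 by at least 2-fold. Camera called 16 lists, 6 up and 10 down. None held with an estimated correlation, and fry called 18. The count was 1262 with near-identical libraries averaged, and 2575 and 2673 without NIC-Prmt6 replicates 1 and 2. Of the 40 named genes that passed, 30 kept their call in each alternative fit. Averaging left 5 milk, 2 cell cycle and no interferon genes higher, and 12 fibroblast, 8 mesenchymal, 7 endothelial, 3 pericyte, 4 adipocyte, 4 NF-kB, 3 p53 list, 4 Notch, 6 matrix protease and 2 immediate early genes lower.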

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

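The rule behind the tests of difference in this part was planned, and it covers only the genes picked for naming, a choice that depends on their results. Among those genes, 16 differences are listed because the gene changed against NIC in opposite directions in a pair of PRMT groups and also differed between those groups in the direct limma comparison; each is a log2 fold change of the first group over the second. Over all tested genes, with or without a direct difference, 28 genes changed against NIC in opposite directions in NIC-Prmt1 and NIC-Carm1, 11 in NIC-Prmt1 and NIC-Prmt6, and 129 in NIC-Carm1 and NIC-Prmt6. No group has 4 or more libraries, so no single library was tested for standing apart.

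NIC-Prmt1 over NIC-Carm1 differed this way in 4 of the genes picked. The growth factor gene Areg differed by 1.47 (adjusted p = 5.08e-05), with 0.73 and -0.74 over NIC. For the matrix gene Fbln1 the difference was 1.14 (adjusted p = 0.00105), with 0.43 and -0.72 over NIC. Keratin Krt7 differed by 1.1 (adjusted p = 5.15e-04), with 0.67 and -0.43 over NIC. The Notch target Nrarp gave 1.32 (adjusted p = 0.00114), with 0.53 and -0.79 over NIC. NIC-Prmt1 over NIC-Prmt6 differed this way in 2 of the genes picked. The EGF receptor gene Egfr differed by -1.19 (adjusted p = 3.60e-04), with -0.61 and 0.58 over NIC. The urokinase gene Plau differed by -0.88 (adjusted p = 0.00220), with -0.36 and 0.53 over NIC, and lost its call without NIC-Prmt6 replicate 2 and on averaging (adjusted p = 0.0673, and from 9.95e-12 to 0.0673 over all alternatives). With near-identical libraries averaged, the other 5 differences passed (adjusted p from 0.00671 to 0.0478). Over NIC, averaging ended the calls of Fbln1, Nrarp and Plau in both groups, of Krt7 in NIC-Carm1 and of Egfr in NIC-Prmt6, while no direction turned. Apart from that of Egfr, each of these calls also ended on leaving out a single library. Of 22 alternatives, 11 ended the call of Fbln1, 10 that of Nrarp and 7 that of Plau in NIC-Prmt1, and 8 that of Krt7 in NIC-Carm1.

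NIC-Carm1 over NIC-Prmt6 differed this way in 10 of the genes picked. The chemokine gene Ccl2 differed by -2.87 (adjusted p = 1.84e-05), with -0.79 and 2.09 over NIC. The Notch ligand gene Dll4 differed by -2.02 (adjusted p = 9.79e-06), with -0.87 and 1.15 over NIC. For Fbln1 the difference was -1.91 (adjusted p = 3.82e-05), with -0.72 and 1.19 over NIC. Prmt6 itself gave -1.77 (adjusted p = 1.69e-04), with -0.68 and 1.09 over NIC. Nrarp gave -1.75 (adjusted p = 1.23e-04), with -0.79 and 0.96 over NIC. The p53 target Eda2r gave -1.68 (adjusted p = 4.27e-04), with -0.86 and 0.82 over NIC. Plau was lower in NIC-Carm1, at -1.62 (adjusted p = 1.82e-05), with -1.09 and 0.53 over NIC. Egfr was lower too, at -1.07 (adjusted p = 8.46e-05), with -0.49 and 0.58 over NIC. The Wnt target Axin2 stood at -1.1 (adjusted p = 7.95e-04), with -0.57 and 0.53 over NIC. Rnf43, a Wnt pathway inhibitor gene, stood at 1.184 (adjusted p = 1.03e-04), with 0.63 and -0.55 over NIC. The fall of Prmt6 in NIC-Carm1 against NIC ended on leaving out any library of NIC or NIC-Prmt6, or NIC-Carm1 replicate 2 or 3 (adjusted p from 0.0652 to 0.173). With near-identical libraries averaged, all 10 differences passed (adjusted p from 0.00413 to 0.0372), but Dll4 alone kept both of its calls over NIC. Averaging ended those of Ccl2, Fbln1, Prmt6 and Nrarp in NIC-Carm1, of Plau in NIC-Prmt6, and of Eda2r, Egfr, Axin2 and Rnf43 in both groups (adjusted p from 0.0502 to 0.189). Each of these 9 genes also lost a call over NIC on leaving out a single library.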

How the results depend on the processing

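The replicate block, leaving out single libraries and the fits other than edgeR, TMM and averaging were planned; those 3 were added after the data were seen. No named gene that passed reversed its direction under any alternative run, and edgeR on recovered reads kept every count within 1.5 times. Which direction held more genes did turn. With upper-quartile rescaling the rises and falls were 1308 and 1238 for NIC-Carm1 against NIC, 2858 and 2965 for NIC-Prmt6 against NIC, 567 and 562 for NIC-Prmt1 against NIC-Prmt6, and 3535 and 2855 for NIC-Carm1 against NIC-Prmt6. With voom they were 1988 and 2099 for NIC-Prmt1 and 3695 and 3970 for NIC-Prmt6 against NIC, and 5494 and 5408 for NIC-Carm1 against NIC-Prmt6. For NIC-Prmt1 against NIC they were 1852 and 1890 with the block, and 2013 and 2030 without NIC-Prmt1 replicate 3. DESeq2 gave 2119 genes for NIC-Prmt1 against NIC-Prmt6. Voom with quality weights gave 4309 for NIC-Carm1 against NIC, 4973 for NIC-Prmt1 against NIC-Prmt6, 10902 for NIC-Carm1 against NIC-Prmt6 and 1508 genes changed the same way in all 3 comparisons with NIC. Fits on the 2 compared groups alone, with fewer samples behind each spread, gave 2775 for NIC-Prmt1 and 1441 for NIC-Carm1 against NIC, and 553 for all 3. They also gave fewer genes for NIC-Prmt1 against NIC-Carm1 (2825). Each comparison with NIC-Prmt6 gave more genes: 6974 against NIC, 1233 against NIC-Prmt1 and 7065 against NIC-Carm1. Averaging the near-identical libraries, which leaves fewer samples, gave 2601, 340 and 1664 for NIC-Prmt1, NIC-Carm1 and NIC-Prmt6 against NIC, 1355 for NIC-Prmt1 against NIC-Carm1, 21 for NIC-Prmt1 against NIC-Prmt6, 1262 for NIC-Carm1 against NIC-Prmt6 and 115 for all 3; the share that rose moved from 41.5% to 26.2% for NIC-Carm1 against NIC, from 51.6% to 65.0% for NIC-Prmt6 against NIC, from 55.7% to 73.1% for NIC-Prmt1 against NIC-Carm1, from 34% to 19.0% for NIC-Prmt1 against NIC-Prmt6 and from 46.8% to 21.2% for NIC-Carm1 against NIC-Prmt6. No library of NIC-Prmt1 or NIC was averaged, yet the count between these groups fell too. All groups share a single estimate of the spread in the main fit. The near-identical pairs add small differences to it, so they can lower the p-values of every comparison. A threshold of at least 2-fold left 182 of the genes shared by all 3. Leaving out each library in turn gave 2277 to 5642 genes for NIC-Prmt1, 709 to 3380 for NIC-Carm1 and 2661 to 6633 for NIC-Prmt6 against NIC, 2626 to 4694 for NIC-Prmt1 against NIC-Carm1, 47 to 2237 for NIC-Prmt1 against NIC-Prmt6, 2575 to 6784 for NIC-Carm1 against NIC-Prmt6 and 358 to 1452 for all 3; where this left a group with 1 library, that library was assumed to vary like the other groups. A replicate block gave 1667 for NIC-Carm1 against NIC and 571 for NIC-Prmt1 against NIC-Prmt6. Residuals of the 13 pairs of same-numbered libraries correlated between -0.132 and 0.10, with 1 above 0.1, which gave no sign of pairing. In groups of 2 libraries the residuals mirror each other, so this check is weak and cannot exclude that the numbers pair the samples. Results for named genes that became weaker numbered 102 on averaging, 60 without either NIC-Prmt6 library, 40 and 44 without NIC replicates 1 and 2, 31 with the 2 groups alone, 23 with the block and 0 without the filter. Apart from these constructions, the cause of the moved counts was not tested. Depth limits genes with few reads in a group, such as Krt25, Krt77 and Ccl24 in NIC and Cr2 in NIC-Prmt6, whose intervals span a wide range. These intervals do not cover differences between libraries of a group, such as those of Krt25 in NIC-Prmt1.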

Other observations

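The gene lists in the first paragraph, and the tests of macrophage number, of near-identical libraries and of cell shares, were chosen only after the result was seen; the simulation of shared NIC libraries and the splits of 6 libraries were planned. Mast cell genes rose in every PRMT group against NIC, 8 of 8 in NIC-Prmt1, 7 of 8 in NIC-Carm1 and 8 of 8 in NIC-Prmt6. Their medians were 3.02, 2.75 and 4.11 on the log2 scale, and the mast cell protease gene Mcpt4 rose by 3.64 ± 0.49, 3.27 ± 0.49 and 4.66 ± 0.53. They summed to 6.12 and 13.8 CPM in NIC and to between 42.8 and 186 CPM elsewhere. Of 15 genes of alternatively activated macrophages, 13 rose and 1 (Arg1) fell in each PRMT group, but several members had already been named among the largest rises, so this count is not independent evidence. Of 13 genes of macrophages and dendritic cells exposed to endotoxin, 8 fell in NIC-Prmt1, 7 in NIC-Carm1 and 6 in NIC-Prmt6, with Il10 at -2.99 ± 0.45, -2.55 ± 0.45 and -2.44 ± 0.49, while Nos2 rose in NIC-Prmt1 (1.48 ± 0.37) and NIC-Prmt6 (2.24 ± 0.40). Of 13 proteasome subunit genes, 10, 4 and 11 fell, with medians of -0.39, -0.33 and -0.56. Of 6 targets of the aryl hydrocarbon receptor, 3 fell in NIC-Prmt1, where 1 rose, 3 fell in NIC-Carm1, and none passed in NIC-Prmt6. Class II histocompatibility genes hardly passed, with 1 of 7 lower in NIC-Prmt1 and NIC-Prmt6 and none in NIC-Carm1, and clock genes went both ways. Hair follicle keratins rose in NIC-Prmt1 (3 of 6), with 621 CPM in replicate 1.

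The shared change against NIC, 989 genes including the macrophage genes, has technical and biological explanations. The simulation of chance from shared NIC libraries gave at most 1 shared gene in 50 draws, but this bound, written beforehand, cannot decide. No group was changed in the draws, so few genes could pass in any comparison, and genes varied independently. A joint shift of only 2 NIC libraries, in handling or batch, would look the same and cannot be told apart from an effect of PRMT overexpression. Fewer macrophages in the NIC libraries would raise all macrophage genes alike. In NIC-Prmt1 the median of 9 general macrophage markers was 0.074 (SD 0.21) where Cd163 and Mrc1 averaged 3.52. In NIC-Carm1 and NIC-Prmt6 the medians were 0.59 (SD 0.34) and 1.03 (SD 0.30) against 3.75 and 5.29. Cd163 and Mrc1 were set apart after the data were seen and were the only list members that rose in NIC-Prmt1, so the gap itself decides nothing. Of the 9 markers, 0 rose and 0 fell in NIC-Prmt1, but the members that rose had been taken out. They showed no sign of fewer macrophages in NIC than in NIC-Prmt1 and cannot exclude it. In NIC-Carm1 1 of the 9 rose and in NIC-Prmt6 6 rose, so a lower number in NIC stays open as part of the change there. A change in the kind of macrophage present, which may come from the transgenes, the animals or the handling, stays open.

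The near-identical pairs, NIC-Carm1 replicates 2 and 3 and NIC-Prmt6 replicates 1 and 2, were weighed as technical repeats. Reading the same library again with counting noise alone would give a chi-square over its degrees of freedom below 1.1, and the lower of both values was 2.46. Aliquots of a single cell preparation cannot be told apart from separate animals that happened to be alike: the largest difference over 11 cell type lists within these pairs, 0.0567 (log2), had to be small in libraries alike over all genes, and the labels do not say. If they are aliquots, the averaged counts may be the fairer ones.

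Stromal genes were higher in NIC-Prmt6 and NIC-Prmt1 than in NIC, and 7 of 12 luminal genes lower in NIC-Prmt6; a lower share of luminal cells would raise all other cell types alike. In NIC-Prmt6, basal genes differed from fibroblast genes by -1.84 in mean log2 fold change (two-sided permutation p = 1.00e-05 over genes, which are not independent, the smallest that the permutations can give). In NIC-Prmt1, pericyte genes differed from general macrophage genes by 1.53 (permutation p = 2.20e-04). The list means were 0.03 (basal) and 1.87 (fibroblast) in NIC-Prmt6, and 1.63 (pericyte) and 0.10 (general macrophage) in NIC-Prmt1, so these lists did not rise alike. The pairs were picked after the values were seen, a different pair in each group, and the macrophage list was without Cd163 and Mrc1. The permutation p-values are therefore no fair test and do not decide on a lower luminal share. A change in single cell types, in the dissection or digestion, or in gene activity within cells stays open and was not tested.

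For the 4199 genes that differed between NIC-Prmt1 and NIC-Carm1, the 6 libraries allow only 10 splits, so no share under 0.1 is possible; the real split had the highest count, and the highest of the others was 0 (limma, with 149 to 2394 genes at an unadjusted p under 0.05).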
